A study of Drosophila melanogaster with 3 samples.

How the data were processed

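Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos. Their age is 8 to 24 hours in the source label; the separate age label holds a single number of hours that disagrees with this and was not used. The embryos carried a fusion of the homeodomain transcription factor B-H1 (BarH1) to enhanced green fluorescent protein, and the labels name an antibody against GFP. The 3 biological replicates form 1 group, so comparisons were made between replicates, with random placements, with sequence flanking the peaks and between kinds of genes. A control experiment named in the labels was not analysed here.

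The authors deposited, for each replicate, a ranked peak list and a thresholded peak list. Per the file headers and accompanying descriptions, the coordinates are on the dm6 assembly, and each replicate's lists derive from that replicate's filtered alignments and 1 further file shared by all 3 replicates, whose role is not stated. The aligner, the peak caller and their versions are not given in the sources used here. Peaks were therefore called per replicate, with 1 input in common, so the lists are not fully independent. The signal of a peak is the value the authors' peak caller gave it; its scale is not stated, and it was used only to describe, rank or filter peaks within a list. The score of a peak, as deposited, comes from an irreproducible discovery rate (IDR) procedure, and the ranked lists give the −log10 of the global IDR that the authors deposited. Every thresholded peak was found in the matching ranked list with a −log10 global IDR of at least 2, an IDR of at most 0.01. The thresholded lists had 1 additional input file of unstated role, and some peaks past that threshold are absent from them.

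For the whole series, 4 ranked lists and 4 thresholded lists, 1 of them named conservative, were derived from all 3 replicates. The conservative list was used as an alternative. The series' ranked lists hold 32 columns of per-sample values that could not be matched to a replicate, and these were not used. Read depth is not given in the sources used here, so the number of reads behind a peak is unknown and no counting interval is given. The number of peaks in a list also depends on depth and on the threshold.

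Peaks on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X were analysed. Arm sequences were those of Release 6 of the genome, the same coordinates as dm6, and genes came from Ensembl release 115, with 13945 protein-coding genes and 23584 distinct transcript start sites (TSSs) of genes other than transposable elements. Peaks of 2 replicates counted as shared when they overlapped by at least 1 bp. Peaks of all replicates were merged where they overlapped, and a merged region with a peak from each of the 3 replicates was called reproducible. Its summit was that of the replicate with the highest percentile of signal there. Overlap and location were compared with 10000 random placements on the same chromosome, for which the smallest possible p is 0.0001. Signal near and far from a TSS was compared with a permutation test of 100000 resamples on the difference of median log2 signal, two-sided, with a smallest possible p of 1e-05. The p values of location and of signal by distance were not adjusted.

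For sequence, 200 bp centred on each summit were compared with 200 bp centred 500 bp away, upstream and downstream in alternation. Presence of a 6-mer on either strand was compared with an exact McNemar test, two-sided, adjusted by Benjamini-Hochberg over the preset and scrambled 6-mers or over all 2080 6-mers per replicate. A 6-mer was called when its adjusted p was below 0.05 in the same direction in 3 of 3 replicates. Peaks were also compared by rank of signal with Fisher's exact test, and chromosomes with an exact binomial test. A protein-coding gene was bound when the summit of a reproducible region lay within 1 kb of one of its TSSs. Bound shares of 18 gene lists were compared with all protein-coding genes by Fisher's exact test, two-sided, adjusted by Benjamini-Hochberg over the lists, beside 10000 random lists matched on gene span in 20 bins. In those lists 4 older symbols were matched to current ones through a table of synonyms, and 2 symbols (tal and Dpt) that fit several genes were left out.

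Genes and 6-mers were named by rule: B-H1 and B-H2; the protein-coding gene with the nearest TSS for the 20 reproducible regions of highest mean percentile of signal; up to 4 bound members of each list, by the same percentile; the preset 6-mers; and the 10 called 6-mers with the highest and 5 with the lowest mean ratio. The samples, tests, lists, naming rule and alternatives were fixed before the data were examined, except where the text says that a choice was made after seeing the data. Summits of non-passing peaks, matched on GC content with or without TSS class, were compared by Fisher's exact test, two-sided. Alternatives were other overlap rules, windows, backgrounds, TSS distances, stricter lists, other gene assignments and leaving out each replicate in turn. Alternatives used 1000 placements, 200 for overlaps by summit or by 50% of both peaks, and 10000 permutations.

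The statistics were tested on simulated data. For 6-mers, summit and flank windows were first swapped at random, which removes their difference in base composition. Of 100 6-mers changed by simulation, 99% were called and 0 of the other 6-mers were called. The simulated change was larger than the observed differences of the Bar class sites TAATTG and TAAACG between summits and flanks. Power for differences as small as those was not measured. That simulation does not show how often a difference in base composition gives a call. For lists placed at random, 7 of 100 had a p under 0.05 for overlap with replicate 2. With 1 enriched gene list simulated among 18, it was called in 100 of 100 simulations and another list in 0. The bound share of that simulated list was above that of any list under the 1 kb rule with regions in all 3 replicates. Power for weaker differences was therefore not measured. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with matplotlib 3.10.9 for figures.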

Results

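The data were peaks of B-H1-eGFP occupancy in whole embryos, aged 8 to 24 hours by the source label, from 3 biological replicates of 1 group. B-H1 is a homeodomain transcription factor of the Bar class, known for roles in the development of sensory organs, eye and leg. The thresholded lists held 2062, 3609 and 2230 peaks in replicates 1, 2 and 3, of which 1971, 3609 and 2199 lay on the 6 chromosome arms. The mean on the arms was 2593 ± 887 peaks (SD, n = 3), and the longest list was 1.83 times the length of the shortest. Peaks covered 709 ± 239 kb (SD, n = 3), with a median width of 300 bp in each replicate. The ranked lists, before the threshold, held 104625, 98054 and 74130 peaks.

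The first question was how far the replicates shared their sites. Of 4085 merged regions on the arms, 1375 had a peak in all 3 replicates, 709 in 2 and 2001 in 1. Replicate 2 alone accounted for 1530 of the regions seen once, against 208 for replicate 1 and 263 for replicate 3. Regions in all 3 replicates made up 71.1% of the regions of replicate 1, 39.6% of those of replicate 2 and 64.3% of those of replicate 3. Replicate 1 shared 81.6% of its peaks with replicate 2 and 78.2% with replicate 3, and replicate 3 shared 80.5% of its peaks with replicate 2 and 70.3% with replicate 1. Replicate 2, with the longest list, shared 45.4% with replicate 1 and 49.6% with replicate 3. Random placement gave means from 0.804% to 1.46% for these 6 comparisons, and each overlap was above all 10000 placements (one-sided permutation by placement, p = 0.0001, the smallest possible, adjusted p = 0.0001). The authors' conservative list for the series overlapped 1368 of the 1375 regions in all 3 replicates, 606 of the 709 in 2 and 672 of the 2001 in 1.

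**Figure D1:**
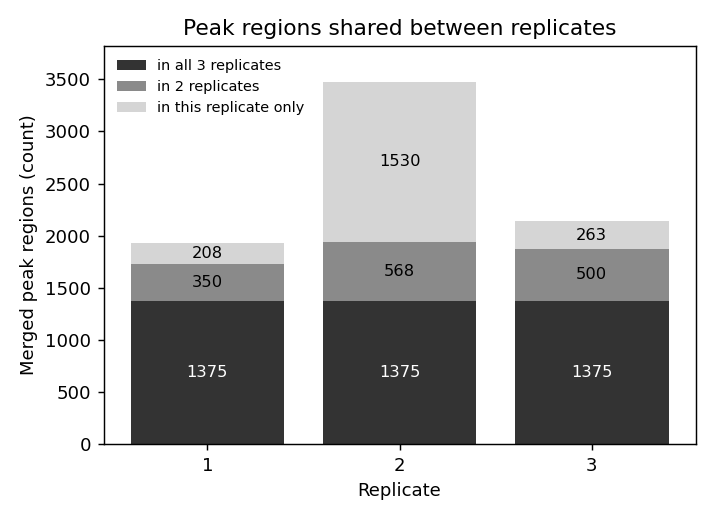
Merged peak regions (count, y axis) in each replicate (x axis), split by the number of replicates with a peak in the region. The 1375 regions in all 3 replicates are the same in each bar, and replicate 2 adds 1530 regions of its own.

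Peak signal was ranked alike in the replicates. Across regions with a peak in both replicates, Spearman's rho was 0.704 for replicates 1 and 2, 0.824 for replicates 1 and 3 and 0.718 for replicates 2 and 3, a mean of 0.749 ± 0.066 (SD over 3 pairs). Pearson's r of log2 signal was 0.790, 0.883 and 0.809. These are correlations across regions, which are not independent replicates, and regions missed by one replicate do not enter, so no p is given.

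Most of the strongest reproducible regions lay near promoters. Of the 20 regions of highest mean percentile of signal, 18 had a summit within 1 kb of a protein-coding TSS and 11 lay upstream of it by at most 200 bp. The first was at X:2703731-2704027 (dm6), an intergenic region 36 bp upstream of the TSS of Ugalt (FBgn0024994), a UDP-galactose transporter gene, at a percentile of 99.98 ± 0.03 (SD, n = 3). The next was at 3L:19590474-19590756, 91 bp upstream of CG14100 (FBgn0036889). The region at 2L:6612556-6612855 lay in an intron of CG11050 (FBgn0031836), 1025 bp from the nearest TSS. Others of the 20 lay at mRpL41 (2R:15217606-15217885, 141 bp upstream) and mRpL23 (3L:2373490-2373744, in the 5′ UTR), which encode mitochondrial ribosomal proteins. The summit at Tcs5, a tRNA modification gene, lay 99 bp from its TSS, that at PNPase, which encodes polynucleotide phosphorylase, 83 bp, and that at eIF6, a translation initiation factor gene, 103 bp.

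The region at X:2137229-2137486 lay in an intron of ph-p (FBgn0004861), a Polycomb group gene, 509 bp from a TSS. That at 3L:22878758-22879047 lay in the 5′ UTR of Chro (FBgn0044324), which encodes the chromodomain protein Chromator. Regions in introns of Adf1 (2R:6662923-6663209) and HmgZ (2R:21703231-21703597), and an intergenic region 3145 bp upstream of tara (3R:16222374-16222621), were also among the 20. The other genes were CenG1A, Art3, CIA30, CG18549, CG5611, CG8320 and px, with summits 101, 121, 107, 135, 119, 83 and 208 bp from the nearest TSS, in that order. The lowest mean percentile among the 20 was 99.09.

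Over whole lists, 59.99% ± 0.51 of summits (SD, n = 3) lay within 1 kb of a TSS, against 23.6% by random placement, a ratio of 2.54 ± 0.03. Each replicate was above all placements (one-sided permutation by placement, p = 0.0001, the smallest possible). Summits were more often upstream: 44.9% ± 4.7 lay within 1 kb upstream of the nearest TSS and 15.1% ± 4.3 within 1 kb downstream (SD, n = 3). Introns held 50.2% ± 0.9 of summits against 42.7% by placement, and 5′ UTRs 8.27% ± 3.26 against 3.38%. Coding sequence held 0.625% ± 0.440 against 16.7%, and 3′ UTRs 1.30% ± 0.21 against 4.95% (one-sided permutation by placement, p = 0.0001 in each replicate for each of these 4 classes). Intergenic sequence held 39.4%, 31.7% and 39.5% of summits in replicates 1, 2 and 3 against 30.5%, and was not past the threshold in replicate 2 (permutation by placement, p = 0.098). In 5′ UTRs lay 433 of the 3609 summits of replicate 2, against 117 of 1971 in replicate 1 and 151 of 2199 in replicate 3.

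**Figure D2:**
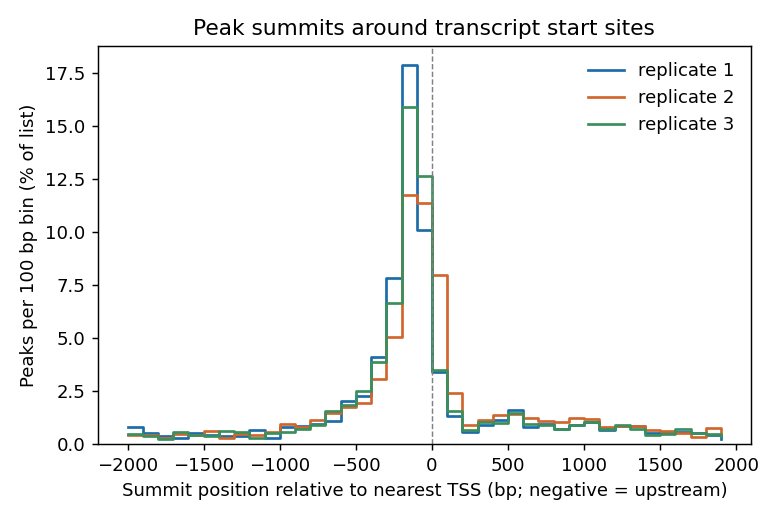
Share of peaks per 100 bp bin (% of each list, y axis) by position of the summit relative to the nearest TSS (bp, x axis, negative values upstream), 1 line per replicate. The lines are highest just upstream of the TSS, where 26.6% ± 3.0 of summits (SD, n = 3) lie within 200 bp.

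Peaks near a TSS had higher signal than peaks farther away in 3 of 3 replicates. The difference of median log2 signal was 0.32 in replicate 1, 0.06 in replicate 2 and 0.26 in replicate 3, a mean of 0.21 ± 0.14 (SD, n = 3). The two-sided permutation p was 1e-05, 0.037 and 1e-05, of which 1e-05 is the smallest possible. With 500 bp as the limit, the difference was no longer past the threshold in every replicate.

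Sequence at the summits was compared next, to ask whether sites of the Bar homeodomain class are more frequent at peaks than beside them. In 200 bp windows they were not called. With 400 bp windows TAAACG was called (1.22 ± 0.03) and the ratio of TAATTG was 0.933 ± 0.034 (SD, n = 3). With 100 bp windows neither was called, and the ratio of TAATTG was 1.29 ± 0.27 (SD, n = 3), from 1.04 in replicate 2 to 1.58 in replicate 1. In 200 bp windows, TAATTG occurred in 19.2% ± 1.7 of summit windows and 17.6% ± 0.5 of flanks (SD, n = 3), a ratio of 1.09 ± 0.13, with adjusted p from 0.0086 to 0.457 and a ratio of 0.954 in replicate 2 (exact McNemar test). TAAACG occurred in 8.76% ± 0.29 and 8.37% ± 0.27, a ratio of 1.05 ± 0.07, with adjusted p from 0.335 to 0.957 (exact McNemar test). The generic homeodomain core TAATTA was called, with a ratio of 1.53 ± 0.26 and a highest adjusted p of 0.001 (exact McNemar test). TATCGA, the core of the element bound by the promoter factor DREF, was called with 10.9% ± 0.6 of summits against 6.52% ± 0.33 of flanks, a ratio of 1.68 ± 0.18 and a highest adjusted p of 2.5e-06 (exact McNemar test). GAGAGA, CAGGTA, CACGTG and TGACTC, standing for GAGA factor, Zelda, E boxes and AP-1, had ratios of 1.03 ± 0.13, 0.821 ± 0.049, 0.710 ± 0.047 and 0.909 ± 0.061 and were not called.

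All 3 scrambled 6-mers were called too: TTAGAT, AACTAG and ATTTAA had ratios of 1.80 ± 0.25, 1.51 ± 0.04 and 1.91 ± 0.36 (SD, n = 3). Summit windows had 35.5% ± 1.9 G or C and flanks 43.2% ± 0.8. The ratios above therefore include a difference in base composition. Against summits of non-passing peaks matched on GC content only, a background chosen after seeing the data, TATCGA was called higher (1.41 ± 0.06), TAATTG was called lower (0.843 ± 0.013) and TAATTA was not called (0.928 ± 0.047; SD, n = 3); the scrambled ATTTAA was still called (1.11 ± 0.02). With matching also on lying within 1 kb of a TSS or not, none of these 3 was called, and TATCGA had a ratio of 1.11 ± 0.08. GAGAGA was called higher against both backgrounds (1.58 ± 0.12 with GC content matched, 1.69 ± 0.22 with both), and CACGTG had ratios of 1.497 ± 0.050 and 1.45 ± 0.38 and was not called. The call of TATCGA was also not kept at summits over 1 kb from a TSS (ratio 1.02 ± 0.15). Among the 60 6-mers of its own base composition, whose median ratio was 1.58, TAATTG had the lowest ratio in 3 of 3 replicates. So did TAATTA among the 14 of its own, whose median ratio was 1.87. TATCGA lay at a percentile of 93.1 among the 102 of its own, whose median ratio was 1.202, and the scrambled AACTAG at 91.4 among the 120 of its own. These comparisons within a composition were chosen after seeing the data.

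**Figure D3:**
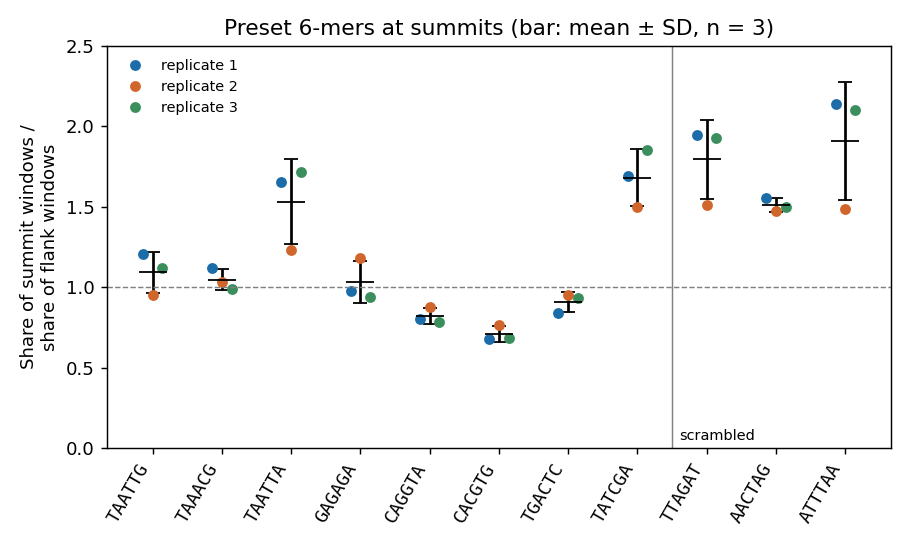
Ratio of the share of summit windows to the share of flank windows with each preset 6-mer (y axis), with 1 point per replicate and bars for the mean ± SD (n = 3); 6-mers to the right of the line are scrambled. TAATTG and TAAACG have mean ratios of 1.09 and 1.05, and the 3 scrambled 6-mers 1.80, 1.51 and 1.91.

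Of all 2080 6-mers, 335 were called higher at summits and 619 lower. The median ratio fell with the number of G or C bases, from 1.81 for 6-mers with 0 to 0.479 for those with 6. Against non-passing summits matched on GC content and TSS class, a background chosen for all 6-mers after seeing the data, 37 were called higher and 11 lower. The 10 with the highest mean ratio to the flanks were ATACTA (2.43 ± 0.60), AGTGTA (2.41 ± 0.21), ACAGTG (2.40 ± 0.24), ATATTA (2.38 ± 0.47), ACACTG (2.31 ± 0.09), ACTGTA (2.24 ± 0.34), TATTAA (2.24 ± 0.57), TTTAAA (2.15 ± 0.46), AATATT (2.11 ± 0.37) and TACTAA (2.10 ± 0.42; SD, n = 3). The 5 with the lowest were CCGGAG (0.251 ± 0.146), GGAGGA (0.271 ± 0.078), CCAGGA (0.275 ± 0.058), CCTCCG (0.276 ± 0.134) and GCCTCC (0.279 ± 0.120).

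The sites TAATTG and TAAACG were more frequent at summits of peaks that passed the threshold than at ranked peaks that did not. TAATTG occurred in 19.2% of passing and 16.1% ± 0.7 of non-passing summits (SD, n = 3), a ratio of 1.19 ± 0.07, higher in 3 of 3 replicates with a highest adjusted p of 0.00663 (Fisher's exact test, two-sided). TAAACG occurred in 8.76% and 7.18% ± 0.12, a ratio of 1.22 ± 0.03, higher in 3 of 3 replicates with a highest adjusted p of 0.0144 (Fisher's exact test, two-sided). That comparison was not matched on base composition or distance to a TSS; with matching on both, the ratios were 0.882 ± 0.031 and 0.941 ± 0.048 and neither was called. Within the thresholded lists, TAATTG occurred in 19.7% ± 2.0 of the top 25% of peaks by signal and 17.5% ± 2.5 of the bottom 25%, and TAAACG in 8.56% ± 0.40 and 9.09% ± 0.78 (SD, n = 3). Neither difference passed, with adjusted p from 0.0876 to 1 (Fisher's exact test, two-sided).

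Chromosome 4 held few peaks and the X chromosome held slightly more than its length gives in replicates 1 and 3. Chromosome 4 had from 2 to 11 peaks, a ratio to the number given by its length of 0.212 ± 0.103 (SD, n = 3), with a highest adjusted p of 2.1e-04 (exact binomial test, two-sided). The ratio for X was 1.17, 0.992 and 1.13 in replicates 1, 2 and 3, with adjusted p of 0.00238, 0.894 and 0.0214 (exact binomial test, two-sided). X was therefore not called in 3 of 3 replicates; without replicate 2 the mean ratio was 1.15. The ratio for 3R was 0.925 ± 0.014, past the threshold in replicate 2 with an adjusted p of 0.00848 (exact binomial test, two-sided). Many peaks past the IDR threshold but absent from the thresholded lists lay on 3R. Of those on the arms, they were 33 of 68, 68 of 112 and 35 of 64 in replicates 1, 2 and 3. The ratio for 3R does not count these absent peaks and was not recomputed with them.

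Genes of glycolysis and of the cytosolic ribosome were bound more often than other genes, and chemoreceptor genes less often. Reproducible regions lay within 1 kb of a TSS of 1102 of 13945 protein-coding genes, 7.90%. Only 802 regions had such a TSS, so 1 summit can count for several neighbouring genes. The tests of gene lists treat such genes as independent. Of 12 glycolysis genes, 5 were bound (41.7%, odds ratio 8.36, p = 0.00151, adjusted p = 0.00906, Fisher's exact test, two-sided). Without replicate 3 the share was 58.3%, against 8.76% of all genes, and the odds ratio 14.7. The 5 included Gapdh2 (X:15867858-15868115, percentile of signal 97.4 ± 2.0), Eno (2L:1727772-1728131, 84.7 ± 3.1), Ldh (3L:6262751-6263067, 78.3 ± 4.6) and Hex-A (X:9585343-9585642, 77.6 ± 12.5; SD, n = 3). Of 92 genes of cytosolic ribosomal proteins, 18 were bound (19.6%, odds ratio 2.87, p = 2.7e-04, adjusted p = 0.00242, Fisher's exact test, two-sided). The share was 30.4% without replicate 1, against 9.37% of all genes, and 53.3% in the conservative list, against 14.4% of all genes. With a summit anywhere in the gene or 5 kb around it the list was not called (27.2% against 20.7% of all genes, adjusted p = 0.221, Fisher's exact test). Those with the highest percentiles were RpL34b (84.8 ± 2.9), RpS27 (84.7 ± 4.9), RpL32 (83.9 ± 8.6) and RpL7 (81.0 ± 12.6; SD, n = 3). Of 180 chemoreceptor genes, 1 was bound, Or88a (3R:14108634-14108966), a share of 0.556% with an odds ratio of 0.0643 (p = 9.7e-06, adjusted p = 1.7e-04, Fisher's exact test, two-sided). In the gene or 5 kb around it, 14 of the 180 had a summit (7.78%, odds ratio 0.320).

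Against random lists matched on gene span, a permutation test, the adjusted p was 0.0492 for glycolysis, 0.0036 for ribosomal proteins and 0.0054 for chemoreceptors. In a permutation test against random lists matched on the number of TSSs, chosen after seeing the data, glycolysis was not called (adjusted p = 0.243), while ribosomal proteins (0.045) and chemoreceptors (0.0072) were. Mean bound shares in those matched lists were 14.5% for glycolysis, against 41.7% observed, 9.64% for ribosomal proteins and 6.31% for chemoreceptors.

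With a summit within 1 kb of a TSS as the rule, no list of developmental genes was called, but other rules called some. The nearest gene at any distance called axon guidance, muscle, trachea and segmentation, with adjusted p from 0.00574 to 0.0184, and the gene span or 5 kb around it called the Notch list and muscle, each with an adjusted p of 0.0189 (Fisher's exact test, two-sided). Under the span rule, as within 1 kb, 1 summit can count for several neighbouring genes, such as those of the E(spl) complex. Fisher's exact test treats these genes as independent. Longer genes also take in more sequence under the span rule, and no match on gene span was run for it. Nor was such a match run for the nearest gene at any distance. Under that rule, genes with more sequence around their TSSs can be nearest to more summits. Within 1 kb, the Bar locus (0 of 2), leg and antenna patterning (0 of 19), Hox genes (0 of 8), epidermis and cuticle (0 of 23) and gut and fat body (0 of 20) had no bound gene, with unadjusted p from 0.254 to 1 (Fisher's exact test, two-sided). Of 57 other homeobox genes, 1 was bound, the heart and muscle factor tin (3R:21378618-21378917, percentile 90.3 ± 6.9). Of 20 proneural and sensory organ genes the bound one was numb, an inhibitor of Notch signalling (84.7 ± 5.2), and of 22 genes of the Notch pathway and E(spl) complex it was E(spl)m3-HLH (69.3 ± 10.5). Of 20 neuroblast genes, brat was bound (94.3 ± 2.3), and of 16 tracheal genes, sty (65.7 ± 11.3; SD, n = 3). Of 24 neuronal genes 3 were bound, the RNA-binding protein gene elav (94.5 ± 1.1), Nrx-1 (66.9 ± 6.8) and dlg1 (59.7 ± 26.4), and of 28 axon guidance genes 2, PlexA (91.9 ± 2.2) and unc-5 (54.9 ± 3.5). Of 15 glial genes 3 were bound, moody (93.2 ± 5.4), Gli (58.7 ± 16.1) and Gs2 (57.2 ± 14.7), and of 26 muscle genes 4, Msp300 (90.2 ± 1.3), sls (75.6 ± 19.6), mbc (45.0 ± 22.3) and rols (34.7 ± 11.9). Of 33 segmentation and signalling genes 3 were bound, spi (86.3 ± 2.5), brk (45.4 ± 26.8) and Wnt6 (20.9 ± 14.1; SD, n = 3). Adjusted p for the 15 lists not called ranged from 0.436 to 1 (Fisher's exact test, two-sided).

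**Figure D4:**
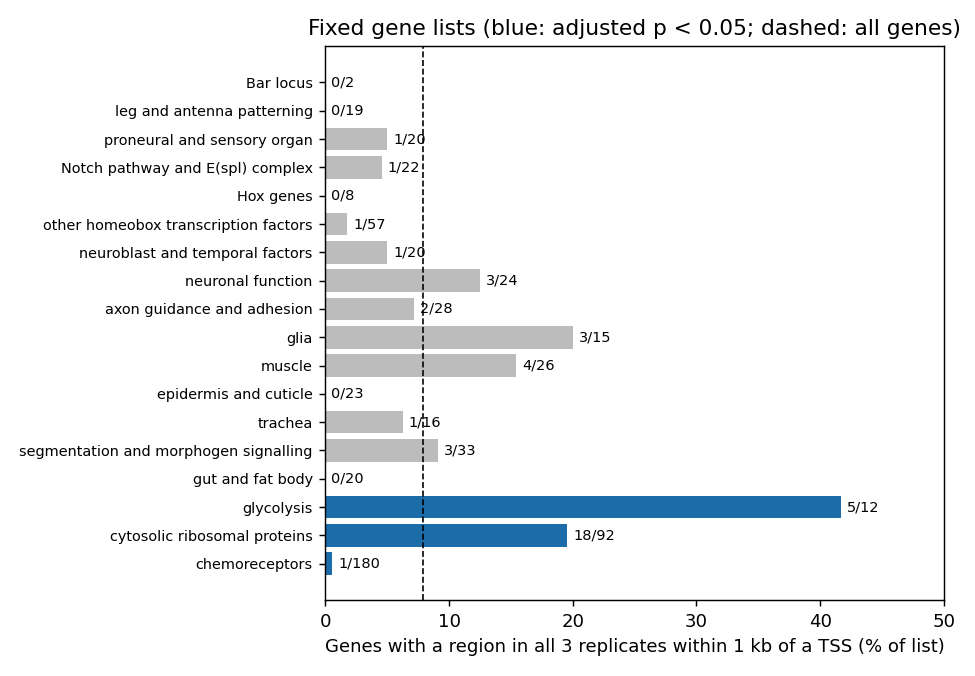
Share of genes bound by a reproducible region (%) in each of the 18 gene lists, with the share of all protein-coding genes for reference. Glycolysis (41.7%) and cytosolic ribosomal proteins (19.6%) lie above the 7.90% of all genes and chemoreceptors (0.556%) below.

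At the Bar locus itself, B-H1 (FBgn0011758, X:17397478-17403278) had a thresholded peak within 1 kb of its TSS in replicate 2 alone, at X:17397141-17397440, with a −log10 global IDR of 2.82 and a percentile of 68.2 in its list. In replicates 1 and 3 the strongest ranked peaks within 1 kb of that TSS had −log10 global IDRs of 0.951 and 0.0993, below the threshold of 2. They lay downstream of the TSS, at X:17398233-17398532 and X:17398245-17398544, and did not overlap the peak of replicate 2. Replicate 3 had a thresholded peak inside the B-H1 gene at X:17402060-17402359. B-H2 (FBgn0004854, X:17314581-17324175) had none within 1 kb of its TSS or within 5 kb of the gene in any of the 3 replicates. Farther upstream of B-H2, peaks of replicates 1 (X:17293437-17293736) and 2 (X:17293344-17293643) overlapped. Peaks of replicates 2 (X:17299497-17299796) and 3 (X:17299492-17299791) overlapped there too.

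**Figure D5:**
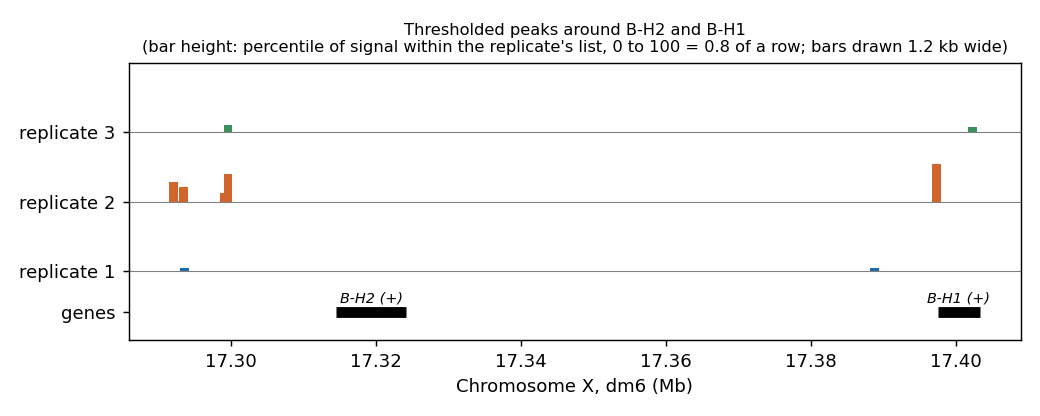
Thresholded peaks of each replicate on the X chromosome around B-H1 and B-H2 (position on dm6, x axis), with bar height giving the percentile of signal within the replicate's list. The peak at the B-H1 TSS is in replicate 2.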

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

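The match on GC content only and the rank of TAATTG and TATCGA among 6-mers of equal composition were tests chosen after the first results were seen; the bounds of all tests were written before their results were seen. The design has 1 group, so no biological explanation was tested.

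Peaks in data outside the comparisons drew attention. Past the IDR threshold but absent from the thresholded lists were 132 peaks in replicate 1, 112 in replicate 2 and 88 in replicate 3. Outside the 6 chromosome arms were 91 thresholded peaks in replicate 1 and 31 in replicate 3, against 0 in replicate 2. Of these, 2 and 1 lay on the Y chromosome, and the rest on X-linked sequences not placed in the arm.

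The absent peaks included strong ones, the strongest of those in all 3 replicates in an intron of cbt (2L:480950-481227), followed by introns of trx and larp. They formed 146 merged intervals on the arms, 31 of them in 3 replicates. Repeats as the whole reason are argued against for absent peaks on the arms. Their soft-masked share exceeded that of thresholded peaks by 3.99 ± 4.35 percentage points (SD, n = 3), under the 10 that was set. The difference was 7.03, -0.99 and 5.92 points in replicates 1, 2 and 3. Off the arms, and not covered by that share, lay 64 of the 132 absent peaks of replicate 1 and 24 of the 88 of replicate 3. A single set of intervals removed from all lists by the authors' filtering may account for the absent peaks, and 4 thresholded peaks overlapped an interval absent from another replicate's list. That number lies between the bounds of 2 and 10 set beforehand, so this stays open.

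Relative to 6-mers of equal composition, TATCGA was high at summits (percentile 93.1, against 91.4 for the scrambled AACTAG) and TAATTG low (1.67), though TAATTG was not less frequent at summits than in flanks on average (ratio 1.09). The generic core TAATTA was likewise the lowest of its own composition (7.14). The many peaks at promoters may account for TATCGA, whose ratio at summits over 1 kb from a TSS was 1.02 ± 0.15 (SD, n = 3). Base composition alone is argued against for TATCGA, whose ratio was 1.41 ± 0.06 against non-passing summits matched on GC content, and 1.11 ± 0.08, no longer called, with TSS class matched too. With both matched, unadjusted p was 0.063 to 0.531 (Fisher's exact test, two-sided), which met the bound set for base composition as the cause. That match cannot part base composition from TSS class, so its outcome was set aside as undecided. For TAATTG, the mean percentile at distal summits was 4.44 ± 4.81 among 6-mers of equal composition. That is under the bound set against promoter peaks hiding sites at distal peaks. With 100 bp windows in replicate 1, however, the percentile was 5 although the ratio to the flanks was 1.58. A low percentile can thus go with a higher frequency at summits, so it cannot decide on hidden distal sites. The ratio of TAATTG at distal summits was 1.05 ± 0.13 (SD, n = 3) and was not called. With matched summits in place of the flanks, the percentile of TAATTG was 3.89 ± 1.92, under the bound set against a high frequency in the flanks. Those matched summits held TAATTG in 21.8% ± 2.0 of windows, against 17.6% ± 0.5 of flanks. The test therefore cannot decide whether a high frequency of TAATTG in the background accounts for its low rank.

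Replicate 2 had more peaks than replicates 1 and 3. Of its 1530 own regions, 46.5% overlapped a ranked peak in both other replicates, against 17.5% ± 0.88 by random placement, so sites below the threshold there may account for part of them. The share lies under the 80% set for the whole difference, which stays open. Of these regions 18.8% had their summit in a 5′ UTR, against 7.05% of regions in all 3 replicates and 6.21% of those in replicate 1 or 3 alone. Read depth is not given, so depth was not tested.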

How the results depend on the processing

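The matched background for all 6-mers, the match of preset 6-mers on GC content only, the matching on TSS number and the minimum signal of 10 were chosen after seeing the data. Of the results that answer a comparison, 81 values under alternatives kept their direction and side of the threshold or stayed within their spread, 12 moved beyond it, 5 reversed, 2 newly passed and 1 no longer passed. Among single 6-mers, lists and regions these were 259 kept, 30 reversed, 8 newly past and 15 no longer past. Overlap and the share within 1 kb of a TSS stayed past the threshold under all alternatives run for them, at 69.4% to 81.6% of the shorter list of each pair and 48.7% to 71.2%. The shares of the longer lists were not recomputed.

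The stronger part of each list, in which fewer peaks enter, gave 749 regions in all 3 replicates. Signal agreement ranged from 0.704 to 0.824 when 1 replicate was left out, highest without replicate 2. With 500 bp, the difference of signal near and far was 0.22 and not past the threshold in every replicate. The ratio for X was 1.06 to 1.15 with 1 replicate left out and passed without replicate 2.

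Called preset 6-mers numbered 4 with 400 bp windows, 1 against matched non-passing summits and 0 at distal summits by exact McNemar tests (1 at an unadjusted p under 0.05). With 100 bp windows 2 were called, but TATCGA (1.45) was not and CACGTG (0.502) was; the conservative list called 3, CACGTG (0.615) among them. TAATTG turned to 0.933 with 400 bp windows and 0.882 against matched summits, and TAAACG was 1.22 and called with 400 bp windows and turned to 0.941 against matched summits. With 100 bp windows TAATTG was 1.29 and not called. Against summits matched on GC content only, 3 were called (TATCGA, GAGAGA and TAATTG), and turned were TAATTG (0.843), TAAACG (0.942), TAATTA (0.928), CAGGTA (1.04), CACGTG (1.497) and TGACTC (1.09). All 6-mers gave 315 calls at distal summits (172 higher, 143 lower), against 860 in the stronger part of each list, and 48 against matched summits (37 higher, 11 lower). Turned in direction were GAGAGA with 1 replicate left out (0.959 to 1.08), with 100 bp windows (0.663) and in the conservative list (0.964); CAGGTA with 400 bp windows (1.03) and at distal summits (1.34); TGACTC with 400 bp windows (1.06) and matched summits (1.09); and, against matched summits, TAATTA (0.952) and CACGTG (1.45).

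With the nearest gene at any distance, 7 lists were called. Shares bound that crossed that of all genes were then 9.09% for Notch, 12.5% for Hox, 10.5% for homeobox, 10% for neuroblast, 25% for axon guidance, 8.70% for epidermis and 31.25% for trachea (all genes 8.12%). Newly called were axon guidance, trachea, muscle (30.8%) and segmentation (27.3%). With the gene span or 5 kb around it they were 50% for Notch, 35.7% for axon guidance and 25% for trachea (all genes 20.7%), Notch and muscle (46.2%) were newly called, and ribosomal proteins were not called (27.2%). Neighbouring genes can share 1 summit under that rule, as they can within 1 kb. In the conservative list the shares that crossed were 18.2% for Notch and 18.75% for trachea, and in regions of at least 2 replicates 12.5% for trachea and 9.09% for segmentation. With 1 replicate left out, trachea ranged from 6.25% to 12.5% and segmentation was 9.09%. The causes of changes under the alternatives were not tested. Read depth is unknown, so what it limits is unknown.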

Other observations

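The 6-mers and windows below were examined after seeing the data. Against non-passing summits matched on GC content and TSS class, 37 6-mers were called higher and 11 lower. The highest mean ratios were those of ACAGTG (2.60 ± 0.12), CAGTGG (2.06 ± 0.26) and ACACTG (2.04 ± 0.20), and the lowest that of CAGGAC (0.439 ± 0.047; SD, n = 3). ACAGTG occurred in 21.7% ± 1.3 of summit windows and 8.34% ± 0.81 of matched windows.

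The shares by distance from the summit, in 100 bp windows, were not tested. TAATTG occurred in 11.3% ± 1.5 at the summit, 7.499% ± 0.141 at 100 bp from it and 9.97% ± 0.19 at 700 bp, and in replicate 2 its share was lower at the summit (9.78%) than at 700 bp (10.2%). TATCGA occurred in 4.93% ± 0.23 at the summit, 6.47% ± 0.48 at 100 bp, 4.48% ± 0.16 at 200 bp and 3.80% ± 0.17 at 1000 bp (SD, n = 3). GAGAGA occurred in 3.61% ± 0.95 at the summit, 8.38% ± 0.02 at 100 bp from it, 7.36% ± 0.36 at 200 bp and 4.18% ± 0.28 at 1000 bp (SD, n = 3). Its ratio to matched non-passing summits was 1.69 ± 0.22 in 200 bp windows, called in 3 of 3 replicates.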
